A study of Rattus norvegicus with 15 samples.

How the data were processed

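RNA from rat lung was sequenced in 15 libraries, 5 each from normal control rats, from rats of a COPD model and from model rats given Wendan Decoction (WDD). Per the labels' protocols, total RNA was extracted with TRIzol, 1 ug of it was used, and libraries were made with the NEBNext Ultra RNA kit. Strand use and the annotation release are not given in the sources used here. Per the submitters' processing notes, reads were trimmed with cutadapt, aligned to the rat genome build Rnor_6.0 with HISAT2 and quantified with StringTie, without stated versions. The deposited values are FPKM as computed by the authors, fragments scaled to gene length and to the mapped fragments of the library, for 22250 genes with Ensembl identifiers and symbols. Genes are named by these symbols, of which 168 occur more than once, and 3950 genes are at 0 in every library. Gene positions are not given, since coordinates for this build were not used here. Read totals were not analysed here, so no counting intervals are given. Relative depth was read from the smallest steps between low FPKM values.

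Values were used as deposited, as log2(FPKM + 1). Genes with an FPKM of at least 1 in at least 5 libraries were kept, which left 13172. All 15 libraries were fitted together by group with limma 3.58.1 (eBayes with trend) in R 4.3.3, and each pair of groups was compared. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all genes tested in a comparison, and a gene was called at an adjusted p under 0.05. Measures of whole libraries were compared by exact permutation tests. Depth estimates, figures and table handling used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

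Before the data were examined, 60 gene lists of cell types and pathways, the comparisons, the tests, the alternatives and the rule for named genes were fixed. Lists with at least 5 measured members, 54 of them, were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Lists with fewer measured members were not tested: those of mast cells and basophils (4 measured), basal cells (3), cartilage and tracheal wall (2), adipocytes (4), platelets (4) and the sex-linked check genes (2). Named genes are the 8 with the largest change up and the 8 down in each comparison, among called genes with a proper symbol whose 5 libraries in a group all lay above or all below those of the other. For each described list they are up to 4 members of lowest p, and for genes called in both comparisons with opposite sign the 6 with the largest changes. Which lists to describe in detail was chosen after their values were seen. The lists of long and short housekeeping transcripts were written by hand from general knowledge before that test was run, and lengths from an annotation were not used.

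On simulated data with the same layout, changes of 0.5, 1 and 2 log2 units were called in 8 of 67, 49 of 67 and 62 of 66 genes for COPD against control, and in 7 of 67, 48 of 67 and 63 of 66 genes for WDD against COPD. Of 12709 unchanged genes, 6, 8 and 0 were called in the comparisons in order. The simulated noise was independent between genes and of equal spread in all groups, without shifts of whole libraries. These rates therefore do not carry over to the real libraries. The libraries were checked for shared material: WDD 4 and WDD 5 were the most alike of 30 pairs within groups, with a dispersion index of 2.32 over 2429 genes against 2.65 to 6.74 for the other pairs. They were kept as separate libraries.

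The alternatives were a pseudocount of 0.1 or 0.5, no filter, a mean FPKM of at least 5, median-of-ratios scaling, quantile normalisation, other variance models, library weights, only the 2 groups compared, the replicate number as a block, a log2 fold change of at least 1, and leaving out each library in turn. Chosen after seeing the data were a scaling to the FPKM sum of all genes and to that sum without mitochondrial genes, averaging WDD 4 and WDD 5, and leaving out COPD 1 and COPD 5 together. Replicate numbers did not pair the libraries: of 15 pairs with the same number, 1 had a correlation above 0.1.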

Results

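Gene expression was measured by RNA sequencing in 15 lung libraries from wild-type rats, 5 in each of 3 groups. The control group held normal rats. The COPD group had received lipopolysaccharide, a bacterial cell wall component, and smoke through the trachea, a model of chronic obstructive pulmonary disease. The WDD group had received the same exposure and Wendan Decoction, a traditional Chinese herbal formula, by gavage. The values were FPKM, fragments scaled to gene length and to the mapped fragments of the library, for 22250 genes, of which 13172 were tested. Read counts were not analysed here. The steps between low FPKM values placed the depth of the libraries between 0.879 (COPD 4) and 1.11 (COPD 2) times that of control 2. The labels do not say that each library came from a separate rat, so p-values measure the spread between these samples only.

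The groups differed in library makeup before any single gene was considered. The 13 mitochondrially encoded genes held 8.11% ± 1.94 of the FPKM sum in control lungs, 44.9% ± 12.4 in COPD lungs and 21.8% ± 2.90 in WDD lungs (mean ± SD, n = 5 each). An exact permutation test gave p = 0.00794 (two-sided) for each pair of groups, the smallest value that 5 against 5 allows. Transcripts of housekeeping genes also separated by length. On the log2(FPKM + 1) scale, the median of 34 long transcripts differed by -1.67 between COPD and control lungs, whereas that of 45 short ones differed by 0.48. Between WDD and control lungs the long ones differed by -0.94 and the short ones by 0.73. The long-minus-short measure thus differed from controls by -2.15 in COPD and by -1.67 in WDD lungs, with p = 0.00794 in both exact permutation tests. It differed by 0.48 between WDD and COPD lungs (exact permutation p = 0.0556). Control 1 stood at -0.71 on this measure, below the other controls. On principal components of the 13172 genes, the first component held 63.6% of the variance, the next 13.1% and the third component 8.49%.

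**Figure D1:**
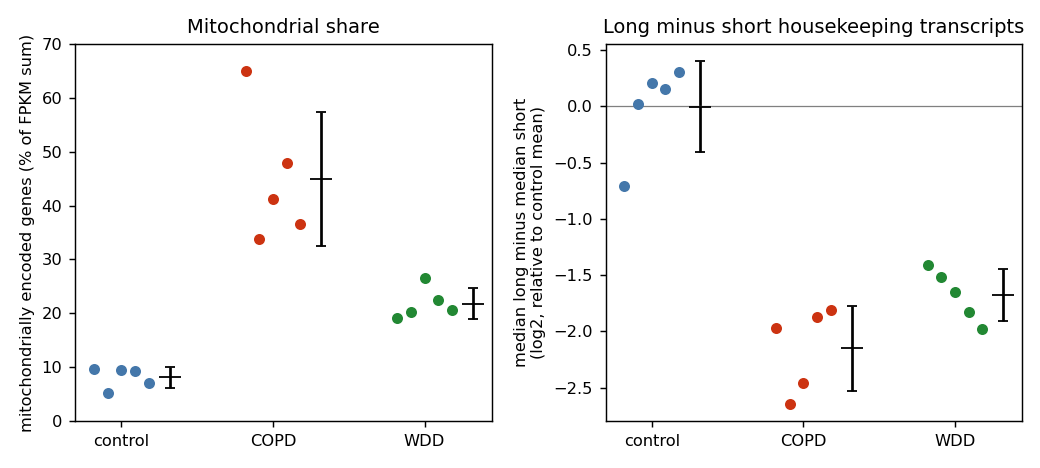
Left, share of the FPKM sum held by mitochondrially encoded genes (percent), and right, median of long minus median of short housekeeping transcripts (log2 units relative to the control mean), with a point per library and a bar for each group mean ± SD (n = 5). The COPD shares lie between 33.7% and 65.0%, above every control and WDD library, and on the right every COPD and WDD library lies below every control.

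The first comparison, COPD against control lungs, addresses the effect of the lipopolysaccharide and smoke exposure. Genes of neutrophils were among those that rose most. S100a8 and S100a9, the subunits of calprotectin, stood at 14.2 ± 7.50 and 37.3 ± 9.68 FPKM in control lungs and at 8453 ± 4944 and 15336 ± 7590 FPKM in COPD lungs (mean ± SD, n = 5), log2 fold changes of 9.04 ± 0.56 and 8.53 ± 0.48 (± SE). Mmp8, a neutrophil collagenase, rose from 1.97 ± 0.584 to 474 ± 105 FPKM, a log2 fold change of 7.32 ± 0.32 (adjusted p = 2.19e-10, limma). Il1r2, a decoy receptor for interleukin-1, rose by 6.66 ± 0.40, and Orm1, an acute-phase protein, by 6.26 ± 0.28. The metallothionein Mt2A rose by 5.93 ± 0.53, and the interferon-induced genes Ifit1 and Ifitm6 by 5.76 ± 0.63 and 5.54 ± 0.54.

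The falls named here were smaller than the rises named above. Fmo2, a flavin monooxygenase abundant in lung, stood at 905 ± 182 FPKM in control and 38.1 ± 48.8 FPKM in COPD lungs, a log2 fold change of -5.25 ± 0.51 (adjusted p = 1.70e-07, limma). The cytochromes P450 Cyp2f4, found in club cells, and Cyp2e1 fell by 4.70 ± 0.44 and 4.54 ± 0.36. Timp3, a metalloproteinase inhibitor bound to the matrix, fell by 4.83 ± 0.34, and Spock2, a matrix proteoglycan, by 4.75 ± 0.50. Ednrb, an endothelin receptor, fell by 4.31 ± 0.31, Selenop, a selenium transport protein, by 4.13 ± 0.28, and Kcnj15, a potassium channel, by 4.12 ± 0.24.

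**Figure D2:**
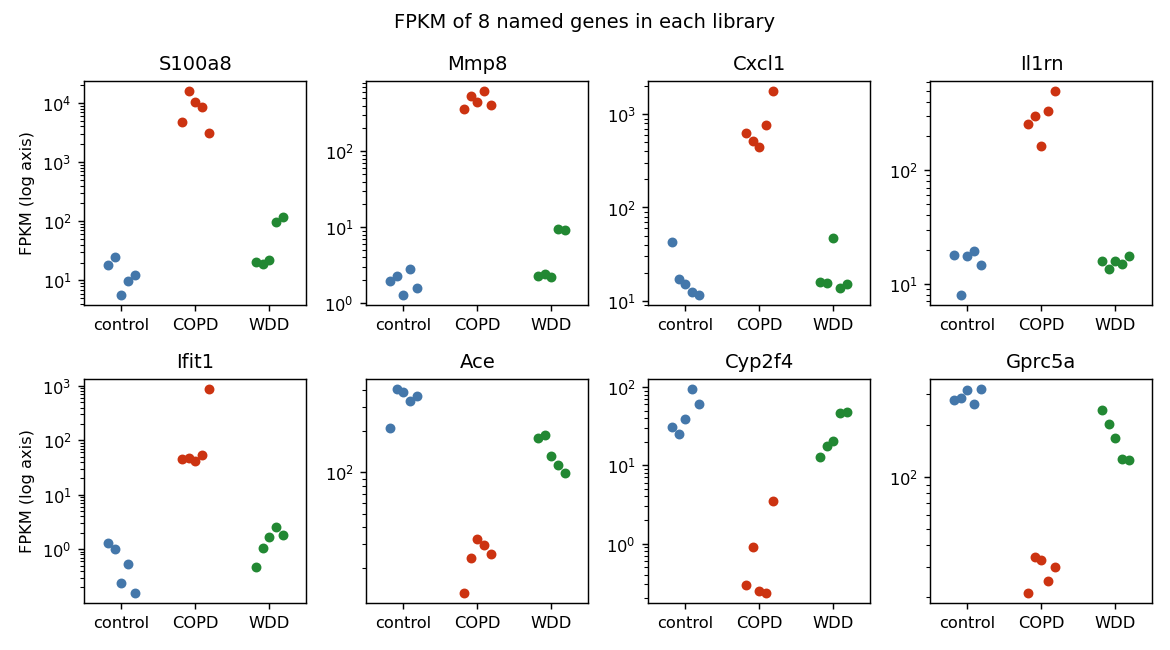
FPKM of 8 named genes (log axis) in the 3 groups, with a point per library, 5 per group. For S100a8, Mmp8, Cxcl1, Il1rn and Ifit1 all 5 COPD libraries lie above all others, and for Ace, Cyp2f4 and Gprc5a all 5 lie below all others.

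The gene lists fixed in advance were tested with camera, which compares a list with all other genes, so each list is given relative to the median log2 fold change of all genes, -0.81. Of 16 measured neutrophil genes, 14 rose, 1 fell and 1 did not pass, with the same counts adjusted over the list alone. Their median lay 4.75 above that of all genes (adjusted p = 2.69e-22, and adjusted p = 0.00832 with an estimated correlation). Besides the genes above, the granulocyte growth factor receptor Csf3r rose by 4.77 ± 0.24 and the gelatinase Mmp9 by 4.69 ± 0.24. Among 26 genes of TLR4 and NF-kappaB signalling, which respond to lipopolysaccharide, 17 rose, 2 fell and 7 did not pass, counts that were equal when adjusted over the list alone. The list median lay 1.93 above all genes (adjusted p = 9.12e-16; adjusted p = 0.154 with an estimated correlation). Examples were the adhesion molecule Selp (4.36 ± 0.40), Bcl3 (2.93 ± 0.25), the lipopolysaccharide-binding protein Lbp (2.18 ± 0.18) and the inhibitory kinase homologue Irak3 (2.11 ± 0.17).

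Of 22 chemokine genes, 12 rose and 5 fell, or 13 and 5 adjusted over the list alone, with a median 2.84 above all genes (adjusted p = 3.49e-10; adjusted p = 0.167 with an estimated correlation). Cxcl1, which attracts neutrophils, rose by 5.30 ± 0.41, and the monocyte chemokines Ccl2 and Ccl7 by 4.22 ± 0.35 and 4.22 ± 0.31. Of 16 inflammatory cytokine genes, 8 rose and 4 fell, the same adjusted over the list alone, with a median 1.60 above all genes (adjusted p = 9.37e-09; adjusted p = 0.107 with an estimated correlation). Il6 rose by 4.56 ± 0.38, Il1rn, an antagonist of interleukin-1, by 4.21 ± 0.26, Osm by 2.35 ± 0.22 and Csf2 by 2.31 ± 0.17. The cytokine median was 1.05, 1.02, 0.96 and 0.85 without COPD 2, 3, 4 and 5 in turn, with the call kept each time. Of 24 interferon response genes, 8 rose and none fell, or 5 adjusted over the list alone. The median lay 1.72 above all genes (adjusted p = 1.97e-10; adjusted p = 0.508 with an estimated correlation), and 0.87 without COPD 5 (adjusted p = 2.21e-06). Relative to the control mean alone, it was 0.02 to 0.47 in the other COPD libraries and -0.42 to 0.39 in controls. Much of the 0.87 thus reflects lower values of the other genes, and fry did not call the list (adjusted p = 0.155). Ifit3 rose by 4.12 ± 0.53, Oasl by 3.51 ± 0.48 and Irf7 by 2.83 ± 0.48. Without COPD 5 these were 3.43, 2.91 and 2.22, and Ifit1 was 4.92. After median-of-ratios scaling 20 TLR4 and NF-kappaB, 15 chemokine, 10 cytokine and 16 interferon response genes rose, and of these lists 1 chemokine gene fell.

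Mitochondrially encoded genes rose with the share described above. Of 13 genes, 12 rose and 1 did not pass, the same adjusted over the list alone, and the median lay 3.74 above all genes (adjusted p = 5.20e-20; adjusted p = 0.107 with an estimated correlation). Mt-atp6 of the ATP synthase stood at 4798 ± 1258 FPKM in control and 37732 ± 7467 FPKM in COPD lungs, a log2 fold change of 2.997 ± 0.25. Mt-cyb, Mt-co3 and Mt-nd3 of the respiratory chain rose by 3.01 ± 0.27, 3.01 ± 0.28 and 2.74 ± 0.24. Ribosomal protein genes depended on the scaling. As deposited, 3 of 24 rose and 2 fell, or 2 and 2 adjusted over the list alone, and the list median lay 0.80 above all genes (adjusted p = 0.000136; adjusted p = 0.604 with an estimated correlation). After median-of-ratios scaling 22 rose and none fell, and under quantile normalisation the list median relative to all genes was -0.08 (adjusted p = 0.619, camera, the highest over all settings). Rpl4 and Rpl27 had log2 fold changes of 0.64 ± 0.15 and 0.62 ± 0.20, and did not pass after scaling to the FPKM sum of all genes (adjusted p = 0.653 and 0.818, limma). Rpl3 and Rpl5 had -0.58 ± 0.12 and -0.51 ± 0.16, which turned to 0.34 and 0.42 after median-of-ratios scaling.

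Lists of alveolar type 1 cells, T cells, and smooth muscle cells and pericytes were lower relative to other genes, whereas those of fibroblasts, endothelial, alveolar type 2 and ciliated cells did not pass (adjusted p = 0.914, 0.194, 0.194 and 0.446, camera). All 14 alveolar type 1 cell genes fell, also adjusted over the list alone, with a median of -1.74 relative to all genes (adjusted p = 0.00292; adjusted p = 0.581 with an estimated correlation). Rtkn2 fell by 3.72 ± 0.23, Gprc5a fell by 3.33 ± 0.19, the tight junction gene Cldn18 fell by 2.58 ± 0.21 and Vegfa, the vascular growth factor, by 2.45 ± 0.22. Of 18 T cell genes, 17 fell, also adjusted over the list alone, with a median of -0.76 relative to all genes (adjusted p = 0.0115; adjusted p = 0.581 with an estimated correlation). The co-receptor Cd4 fell by 3.87 ± 0.26, the transcription factor Tcf7 fell by 3.28 ± 0.22, and Cd3e and Cd247 of the T cell receptor complex by 3.12 ± 0.19 and 1.81 ± 0.18. This call ended with library weights (adjusted p = 0.0529, camera).

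All 15 genes of smooth muscle cells and pericytes fell, also adjusted over the list alone, with a median of -1.08 relative to all genes (adjusted p = 0.0174; adjusted p = 0.590 with an estimated correlation). Notch3 fell by 3.12 ± 0.23, Lmod1 by 2.36 ± 0.24, Rgs5 by 2.35 ± 0.20 and Cspg4 by 2.03 ± 0.19. This call ended when genes with a mean FPKM under 5 were left out (adjusted p = 0.0538, camera). Of 17 genes of angiogenesis and vascular tone, 15 fell, with a median of -0.80 relative to all genes (adjusted p = 0.0269; adjusted p = 0.581 with an estimated correlation). Ace, the angiotensin-converting enzyme, stood at 339 ± 76.0 FPKM in control and 25.0 ± 7.46 FPKM in COPD lungs (-3.73 ± 0.24), and the vascular growth factor receptor Kdr fell by 2.98 ± 0.22. Of 17 genes of tight junctions and epithelial adhesion, 15 fell, with a median of -0.90 relative to all genes (adjusted p = 0.0269; adjusted p = 0.658 with an estimated correlation). F11r fell by 2.94 ± 0.25, the desmosomal gene Dsp by 2.05 ± 0.16 and Esrp1, a splicing factor of epithelia, by 1.40 ± 0.14. The counts of these last lists were also 15 and 15 adjusted over the list alone. After median-of-ratios scaling 11 angiogenesis genes fell, and of the tight junction genes 14 fell and 2 rose. The angiogenesis call ended after scaling to the FPKM sum of all genes (adjusted p = 0.0681, camera). Beside these lists, the long housekeeping transcripts described above differed by -1.67 and the short ones by 0.48 between COPD and control lungs.

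In all, 9833 of 13172 genes passed an adjusted p of 0.05 in limma, 1084 higher and 8749 lower in COPD lungs. In 7416 genes all libraries of a group lay above all of the other on the deposited values. The median FPKM of the tested genes was 6.42 in COPD and 12.7 in control lungs (group means), so whole libraries were shifted. The 0.794% of genes given by chance without such a shift is therefore no measure for this count. The split depended on the scaling: 3947 genes were higher and 4296 lower after median-of-ratios scaling, where the median of all genes was -0.05, and 481 were higher and 10883 lower after scaling to the FPKM sum of all genes, where it was -1.27. With mitochondrial genes left out of that sum 1479 were higher and 7813 lower, and the median was -0.65. Under both the deposited and the median-of-ratios values, 1084 genes were called higher and 4296 lower, while 515 were called in opposite directions. Of 54 lists tested, 21 passed, 16 up and 5 down relative to other genes, of which 1 passed with an estimated correlation. The balance of directions turned with the setting: 12 up and 10 down after median-of-ratios scaling, 8 and 13 under quantile normalisation, and 7 and 35 in fry. For 8 of the 21 the list median or mean had another sign than the test: ribosomal proteins, apoptosis, NRF2 oxidative stress response, matrix metalloproteinases and elastolytic proteases, inflammasome and pyroptosis, MAPK and AP-1 immediate early genes, hypoxia and glycolysis, and cell cycle and proliferation. With an estimated correlation their adjusted p lay between 0.147 (apoptosis) and 0.708 (cell cycle), and those of the lists of cardiac and skeletal muscle and of lymphoid follicle formation, both up, were 0.147 and 0.215.

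**Figure D3:**
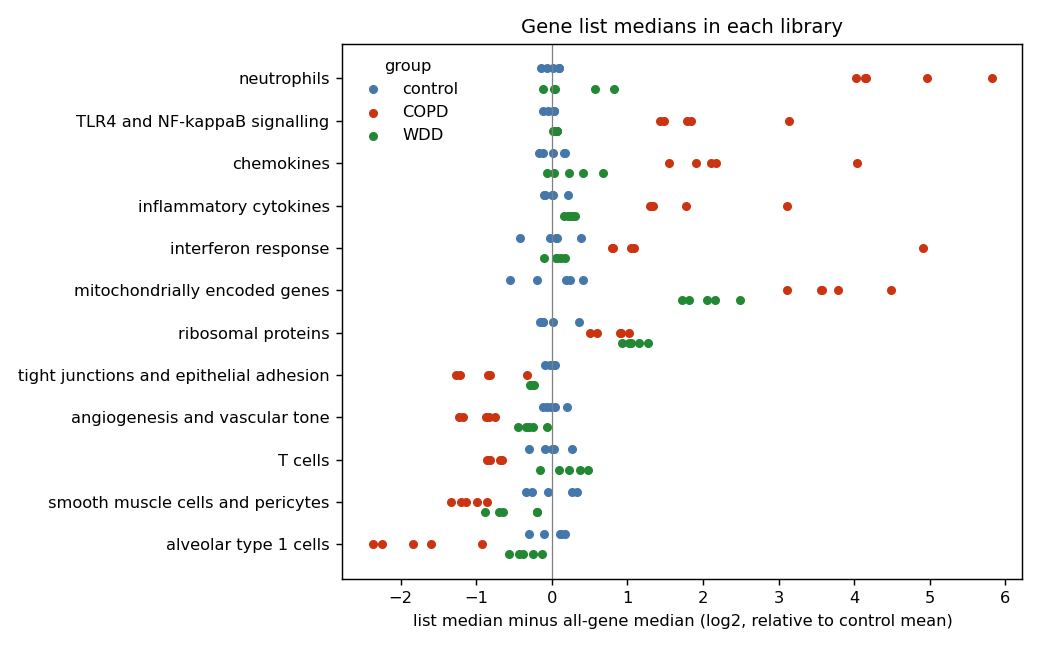
Median of each gene list in each library (log2 units) relative to the control mean and to the median of all genes in that library, with a point per library, 5 per group. Neutrophil genes of all 5 COPD libraries lie above those of all control and WDD libraries, and the interferon response median of COPD 5 lies far above that of the other COPD libraries.

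The second comparison, WDD against COPD lungs, addresses the effect of the decoction in exposed rats. Several genes with large rises in COPD lungs were far lower in WDD lungs. S100a8 stood at 54.7 ± 47.8 FPKM in WDD lungs, a log2 fold change of -7.48 ± 0.56 from COPD lungs (adjusted p = 6.01e-08, limma), and S100a9 fell by 7.02 ± 0.48. Mmp8 fell by 6.48 ± 0.32 to 5.10 ± 3.83 FPKM, Il1r2 fell by 6.37 ± 0.40, Orm1 by 6.12 ± 0.28 and Ifitm6 fell by 5.28 ± 0.54. Ebi3, a subunit of interleukin-27, fell by 5.33 ± 0.41, and Cxcl1 by 5.18 ± 0.41. Among the WDD libraries, S100a8 stood at 95.6 and 117 FPKM in WDD 4 and WDD 5 and at 18.7 to 22.1 FPKM in the other 3.

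Among the named genes that rose, Fmo2 stood at 545 ± 91.1 FPKM in WDD lungs, a log2 fold change of 4.54 ± 0.51 (adjusted p = 3.05e-06, limma). Cyp2e1, Cyp2f4 and Cyp2a1 rose by 4.48 ± 0.36, 3.90 ± 0.44 and 3.67 ± 0.60. Scgb3a2, a club cell secretoglobin, rose by 3.64 ± 0.57, and Jchain, the joining chain of secreted antibodies, by 3.73 ± 0.38. The list of club and goblet secretory cells did not pass (6 of 10 genes rose, adjusted p = 0.739, camera). Cytl1, a secreted cytokine-like protein, and Ccn2, a matrix signalling protein, rose by 3.80 ± 0.25 and 3.63 ± 0.45.

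The median log2 fold change of all genes was 0.54, and lists are given relative to it. Of 16 neutrophil genes, 14 fell, 1 rose and 1 did not pass, the same adjusted over the list alone, with a median of -4.48 relative to all genes (adjusted p = 5.21e-27; adjusted p = 0.00352 with an estimated correlation). Csf3r fell by 4.86 ± 0.24 and Mmp9 by 4.60 ± 0.24. Of 26 TLR4 and NF-kappaB genes, 18 fell and none rose, or 19 adjusted over the list alone, with a median of -1.90 relative to all genes (adjusted p = 7.98e-24; adjusted p = 0.0903 with an estimated correlation). Selp fell by 4.14 ± 0.40, Bcl3 by 2.99 ± 0.25, Irak3 by 2.33 ± 0.17 and Lbp by 2.06 ± 0.18. Of 22 chemokine genes, 10 fell and 3 rose, the same adjusted over the list alone, with a median of -1.99 relative to all genes (adjusted p = 2.23e-10; adjusted p = 0.184 with an estimated correlation), or -1.26 without COPD 5. Ccl2 and Ccl7 fell by 4.09 ± 0.35 and 3.80 ± 0.31, whereas Ccl5, a T cell chemokine, rose by 2.03 ± 0.25.

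Of 16 inflammatory cytokine genes, 10 fell and 4 rose, the same adjusted over the list alone, with a median of -1.56 relative to all genes (adjusted p = 2.60e-10; adjusted p = 0.0697 with an estimated correlation). Il6 fell by 4.52 ± 0.38, Il1rn fell by 4.15 ± 0.26, Osm by 2.27 ± 0.22 and Csf2 by 2.10 ± 0.17. Of 24 interferon response genes, 8 fell and none rose, or 5 adjusted over the list alone, with a median of -1.64 relative to all genes (adjusted p = 1.50e-12; adjusted p = 0.405 with an estimated correlation), or -0.80 without COPD 5. In fry this list was not called (adjusted p = 0.0691). Ifit1, Oasl, Ifit3 and Irf7 had log2 fold changes of -5.16 ± 0.63, -3.75 ± 0.48, -3.74 ± 0.53 and -2.85 ± 0.48. After median-of-ratios scaling 24 TLR4 and NF-kappaB, 12 chemokine, 10 cytokine and 15 interferon response genes fell, and 2 chemokine genes and 1 cytokine gene rose. Of 13 mitochondrially encoded genes, 11 fell and none rose, the same adjusted over the list alone, with a median of -1.56 relative to all genes (adjusted p = 2.23e-10; adjusted p = 0.284 with an estimated correlation). Mt-co1 and Mt-co2 fell by 1.35 ± 0.29 and 1.26 ± 0.30, Mt-atp6 and Mt-co3 by 1.19 ± 0.25 and 1.15 ± 0.28. Under quantile normalisation none of these genes passed, with Mt-co1 at -0.06 and Mt-co3 at 0.00. That normalisation gives each rank the same value in every library, so genes at the highest ranks can hardly differ under it. Without a filter on low values Mt-co1, Mt-co2 and Mt-co3 did not pass (adjusted p = 0.125, 0.0884 and 0.121, limma).

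All 14 alveolar type 1 cell genes rose, also adjusted over the list alone, with a median 1.46 above all genes (adjusted p = 0.000314; adjusted p = 0.485 with an estimated correlation). Gprc5a rose by 2.53 ± 0.19, the water channel Aqp5 by 2.40 ± 0.28, Rtkn2 by 2.26 ± 0.23 and Vegfa by 2.02 ± 0.22. Of 18 T cell genes, 17 rose, also adjusted over the list alone, with a median 1.01 above all genes (adjusted p = 8.91e-05; adjusted p = 0.338 with an estimated correlation). Cd3d, Tcf7 and Cd247 rose by 2.93 ± 0.22, 2.73 ± 0.22 and 2.16 ± 0.18, and Cd3e rose from 0.793 ± 0.443 to 13.2 ± 2.68 FPKM. Of 17 genes of tight junctions and epithelial adhesion, 15 rose, with a median 0.66 above all genes (adjusted p = 0.0108; adjusted p = 0.616 with an estimated correlation), among them F11r (2.27 ± 0.25), Cldn18 (1.81 ± 0.21), the keratin Krt8 (1.77 ± 0.17) and Dsp (1.20 ± 0.16). Of 17 genes of angiogenesis and vascular tone, 15 rose, with a median 0.61 above all genes (adjusted p = 0.0483; adjusted p = 0.587 with an estimated correlation), among them Ace (2.47 ± 0.24), Ednrb (2.42 ± 0.31) and Kdr (2.19 ± 0.22). Adjusted over the list alone, these last lists also had 15 and 15 genes higher, and after median-of-ratios scaling 12 and 9, with 1 tight junction gene lower. Beside these lists, the long housekeeping transcripts differed by 0.73 and the short ones by 0.25 between WDD and COPD lungs. The angiogenesis call ended without COPD 3, COPD 4, COPD 5 or WDD 3 (adjusted p = 0.0556, 0.0556, 0.0544 and 0.0564, camera) and without COPD 1 and COPD 5 together (adjusted p = 0.0518, camera). It also ended when genes with a mean FPKM under 5 were left out (adjusted p = 0.0625, camera) or libraries were scaled to the FPKM sum of all genes (adjusted p = 0.0654, camera).

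In all, 8399 genes passed in limma, 7526 higher and 873 lower in WDD than in COPD lungs, and the libraries of 5934 genes did not overlap on the deposited values. Whole libraries were shifted here too (median FPKM 9.99 in WDD and 6.42 in COPD lungs, group means), so the 0.794% by chance is no measure for this count. After median-of-ratios scaling 3075 were higher and 2819 lower, with the median of all genes at 0.03, and after scaling to the FPKM sum of all genes 8682 were higher and 683 lower, with the median at 0.67. With mitochondrial genes left out of that sum 4544 were higher and 1511 lower, with the median at 0.26. Under both the deposited and the median-of-ratios values, 3075 genes were called higher and 873 lower, while 56 were called in opposite directions. Of 54 lists, 17 passed, 4 up and 13 down relative to other genes, of which 1 passed with an estimated correlation. This balance was 10 up and 13 down after median-of-ratios scaling, 12 and 10 under quantile normalisation, 12 and 14 without a filter, 10 and 15 when scaled without mitochondrial genes, and 30 and 7 in fry. In 5 of them the list median or mean had another sign than the test: NRF2 oxidative stress response, MAPK and AP-1 immediate early genes, inflammasome and pyroptosis, matrix metalloproteinases and elastolytic proteases, and cell cycle and proliferation. With an estimated correlation their adjusted p lay between 0.141 (matrix metalloproteinases) and 0.660 (cell cycle), and those of apoptosis and of hypoxia and glycolysis, both down, were 0.102 and 0.439. The median of the matrix metalloproteinase list relative to all genes was -0.46, and -0.08, -0.13, -0.12 and -0.19 without COPD 2, 3, 4 and 5 in turn.

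How far WDD moved the genes that the exposure had moved was read from the overlap of both comparisons. Of the 13172 genes, 7373 were called in both with opposite sign, 633 higher and 6740 lower in COPD lungs, and 44 were called in both with the same sign. S100a8, S100a9, Mmp8, Il1r2, Orm1 and Ifitm6 had the largest changes in both among genes open to naming. Independent lists of the same sizes would share 71.8 and 4999 genes in these directions. Both comparisons use the COPD libraries. With these split between the comparisons, in all 20 ways, 5027 to 6528 genes were called with opposite sign, 1.27 to 1.54 times as many as independent lists would share. After median-of-ratios scaling these were 2915 to 3792 genes, 1.93 to 2.90 times as many. With all COPD libraries in both comparisons the overlap after that scaling was 4777 genes, and 3043 genes were called with opposite sign under both scalings, 633 higher and 2410 lower in COPD lungs. Across genes, which are not independent replicates, the fold changes of the comparisons had a correlation of -0.826 (jackknife SE 0.0399), between -0.821 and -0.585 with the COPD libraries split. The simulated unchanged groups gave a mean correlation of -0.492 and reached -0.846, so on the deposited values the correlation does not exceed what the shared libraries alone can give. After median-of-ratios scaling it was -0.846, against a lowest simulated value of -0.826. The simulations gave all groups equal spread, whereas COPD libraries varied more, with a mitochondrial share SD of 12.4 against 1.94 (control) and 2.90 (WDD). A more variable shared group would push the simulated correlation further below 0, so -0.826 is not a firm limit. The covariance was -0.691 against a mean of -0.0325 in the simulations, a difference of -0.658, and the lowest simulated value was -0.0864. With the COPD libraries split, the median covariance was -0.645.

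**Figure D4:**
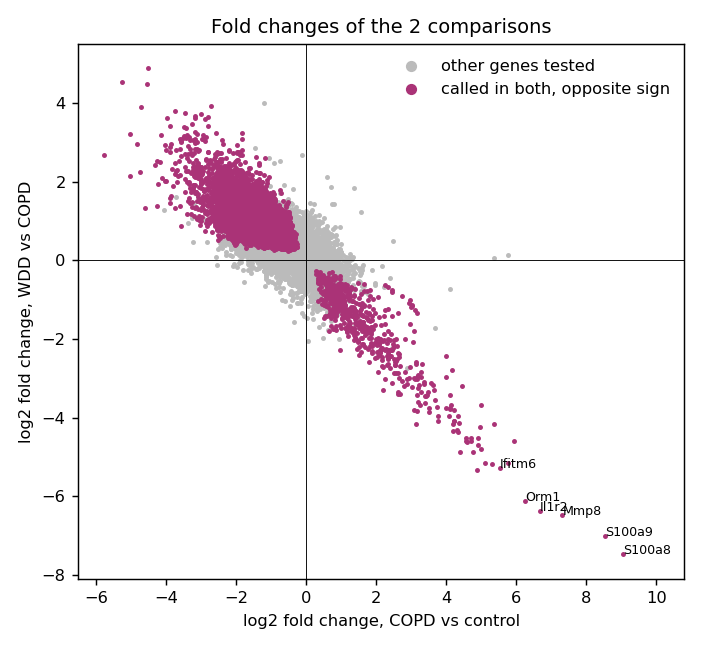
Log2 fold change of each of the 13172 genes in COPD against control lungs (horizontal) and in WDD against COPD lungs (vertical), with the 7373 genes called in both with opposite sign in colour. Both axes share the COPD libraries, which by itself slopes the cloud downwards, and the named genes are those with the largest changes in both.

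The third comparison, WDD against control lungs, addresses how far treated rats remained from normal ones. Mitochondrially encoded genes were the named genes that rose most: Mt-nd2 stood at 3226 ± 1122 FPKM in control and 12002 ± 2354 FPKM in WDD lungs, a log2 fold change of 1.96 ± 0.29 (adjusted p = 0.000127, limma). Mt-cyb, Mt-co3, Mt-co2 and Mt-nd1 rose by 1.89 ± 0.27, 1.86 ± 0.28, 1.84 ± 0.30 and 1.84 ± 0.27, and Mt-nd3, Mt-co1 and Mt-atp6 by 1.82 ± 0.24, 1.82 ± 0.29 and 1.81 ± 0.25. Without a filter on low values Mt-co1 did not pass (adjusted p = 0.0632, limma). Zbtb16, a zinc finger transcription factor, fell most of the named genes, from 29.4 ± 10.7 to 3.56 ± 1.20 FPKM (-2.70 ± 0.29, adjusted p = 2.41e-05, limma). The transporters Slc7a2 and Slc6a6 fell by 2.68 ± 0.52 and 2.49 ± 0.26, Spock2 fell by 2.496 ± 0.50, the cytokine receptor Lifr by 2.45 ± 0.32, Crim1 by 2.40 ± 0.26, the TGF-beta receptor Tgfbr2 by 2.35 ± 0.31 and the hyaluronidase Hyal1 by 2.32 ± 0.30.

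The median of all genes was -0.23, and 5 of 54 lists passed, 4 up and 1 down relative to it, of which 0 passed with an estimated correlation. At an unadjusted p under 0.05 with an estimated correlation, 3 lists passed, and 13 passed in fry, 2 up and 11 down, which asks whether the genes of a list moved, on balance, one way. Under quantile normalisation 13 passed in camera, 3 up and 10 down. Of 13 mitochondrially encoded genes, 12 rose and none fell, the same adjusted over the list alone, with a median 2.05 above all genes (adjusted p = 1.80e-15; adjusted p = 0.523 with an estimated correlation). Of 24 ribosomal protein genes, 21 rose and none fell, or 22 adjusted over the list alone, with a median 1.08 above all genes (adjusted p = 1.22e-18; adjusted p = 0.523 with an estimated correlation). Rpl11, Rpl23 and Rpl4 rose by 1.08 ± 0.19, 0.97 ± 0.17 and 0.89 ± 0.15, of which Rpl23 and Rpl4 no longer passed under quantile normalisation (adjusted p = 0.0504 and 0.371, limma). Of 21 nuclear-encoded oxidative phosphorylation genes, 9 rose and 2 fell, or 10 and 2 adjusted over the list alone and 15 and 1 after median-of-ratios scaling, with a median 0.55 above all genes (adjusted p = 4.32e-05; adjusted p = 0.892 with an estimated correlation). The complex I genes Ndufa4, Ndufa2 and Ndufb3 rose by 1.15 ± 0.28, 1.14 ± 0.22 and 1.09 ± 0.24, and Atp5f1a of the ATP synthase fell by 0.59 ± 0.12.

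Of 13 antioxidant enzyme genes, 2 rose and none fell, the same adjusted over the list alone and 7 after median-of-ratios scaling, with a median 0.41 above all genes (adjusted p = 0.00691; adjusted p = 0.892 with an estimated correlation). These were Txn1, a thioredoxin (1.24 ± 0.24), and Sod1, a superoxide dismutase (0.77 ± 0.25, adjusted p = 0.0224, limma). The Sod1 call ended without control 3, control 5 or WDD 5 (adjusted p = 0.0624, 0.0551 and 0.0641, limma). It also ended with WDD 4 and WDD 5 averaged (adjusted p = 0.0555, limma) and after scaling to the FPKM sum of all genes (adjusted p = 0.183, limma). The list call ended under quantile normalisation (adjusted p = 0.423, camera). Prdx5 (0.54 ± 0.22) and Txn2 (0.41 ± 0.17) had adjusted p of 0.0672 and 0.0636 and passed after median-of-ratios scaling (adjusted p = 0.00818 and 0.00139, limma). At the same fold changes on the deposited values, both also passed with only the 2 groups compared (adjusted p = 0.0079 and 0.00755, limma). Both passed without COPD 5 too (adjusted p = 0.0375 and 0.0445, limma), so their miss was not a matter of scaling alone. Of 20 genes of PI3K, AKT and mTOR signalling, 13 fell and none rose, or 14 adjusted over the list alone and 8 after median-of-ratios scaling, where 1 rose, with a median of -0.36 relative to all genes (adjusted p = 0.00721; adjusted p = 0.892 with an estimated correlation). The forkhead transcription factors Foxo1 and Foxo3 fell by 1.87 ± 0.21 and 1.64 ± 0.24, Rictor of the mTOR complex by 1.65 ± 0.21 and Tsc1 by 1.25 ± 0.19. Control 1 stood nearer to the WDD libraries than the other controls did, with a median of this list of -0.27 against 0.04 to 0.12 relative to the control mean, and it was also the lowest control for Foxo1, Tsc1 and the long-minus-short measure (-0.71). The housekeeping transcripts described above moved beside these lists: the median of the short ones differed by 0.73 and that of the long ones by -0.94 between WDD and control lungs.

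In all, 4915 genes passed in limma, 836 higher and 4079 lower in WDD than in control lungs, and the libraries of 5024 genes did not overlap on the deposited values. Whole libraries were shifted here too (median FPKM 9.99 in WDD and 12.7 in control lungs, group means), so the 0.794% by chance is no measure for this count. After median-of-ratios scaling 2071 were higher and 2262 lower, with the median of all genes at 0.00, and after scaling to the FPKM sum of all genes 304 were higher and 7581 lower, with the median at -0.58. With mitochondrial genes left out of that sum 645 were higher and 5349 lower, with the median at -0.37. Under both the deposited and the median-of-ratios values, 836 genes were called higher and 2262 lower, and none in opposite directions. The fit shares its estimate of spread over all 3 groups, so the counts and SEs of this comparison also carry the spread of the COPD libraries. With only the 2 groups compared, 7211 genes were called, 1642 higher and 5569 lower. The count was 6075 without COPD 5 and 8209 with library weights.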

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

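In groups of 5 libraries, the gap of the highest or lowest library to its neighbour was divided by the range of the group, and ratios above the critical value of 0.71 are given here as values. Gene ratios were computed on log2(FPKM + 1), while the levels printed beside them are FPKM. These were 30 of 354 groups for named genes and 8 of 162 for gene lists, while chance gives about 5%. The tests on COPD 5 in the closing paragraph of this part were chosen after its values were seen.

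COPD 5 stood above the other COPD libraries for the interferon-induced genes Ifit1 (879 FPKM against 42.2 to 54.5, ratio 0.917), Irf7 (904 against 86.7 to 124, ratio 0.847), Oasl (257 against 25.7 to 41.5, ratio 0.794) and Ifit3 (1637 against 97.8 to 192, ratio 0.761). It also stood above them for Ccl2 (314 FPKM, ratio 0.822), Sod2 (1774 FPKM, ratio 0.766), Slc7a2 (15.8 FPKM, ratio 0.938), Rictor (2.14 FPKM, ratio 0.881), Spock2 (11.97 FPKM, ratio 0.734) and Cyp2a1 (4.71 FPKM, ratio 0.727). Its list medians were higher for interferon response (ratio 0.885) and chemokines (ratio 0.776) and lower for cell cycle and proliferation (ratio 0.873). COPD 1 stood below the others for Vegfa (44.1 FPKM against 96.6 to 102, ratio 0.935) and for the TGF-beta signalling list (ratio 0.743).

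Control 1 stood below the other controls for Fmo2 (580 FPKM against 970 to 997, ratio 0.949), Tgfbr2 (26.7 FPKM, ratio 0.884), Timp3 (403 FPKM, ratio 0.857), Tsc1 (5.65 FPKM, ratio 0.804), Lifr (9.62 FPKM, ratio 0.775), Crim1 (33.6 FPKM, ratio 0.737), Foxo1 (9.91 FPKM, ratio 0.73) and the list of PI3K, AKT and mTOR signalling (ratio 0.786). It stood above them for Prdx5 (194 FPKM, ratio 0.84) and Txn1 (374 FPKM, ratio 0.769). Its long-minus-short measure, -0.71, was the lowest of the controls. Control 2 stood above the others for Gpx3 (1146 FPKM, ratio 0.727) and below them for the plasma cell list (ratio 0.739).

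WDD 3 stood above the other WDD libraries for Cxcl1 (47.1 FPKM against 13.6 to 15.8, ratio 0.883), Sftpb (2834 FPKM, ratio 0.847) and Cd74 (1991 FPKM, ratio 0.84). It stood below them for Spock2 (6.002 FPKM, ratio 0.842) and for the lists of eosinophils and type 2 response (ratio 0.863) and interferon response (ratio 0.727). WDD 1 was high for Tcf7 (38.1 FPKM, ratio 0.849) and Tgfbr2 (13.1 FPKM, ratio 0.814). WDD 5 was low for Ebi3 (0.528 FPKM, ratio 0.916) and high for Cspg4 (4.47 FPKM, ratio 0.741), and WDD 4 was low for Ccl4 (8.004 FPKM, ratio 0.78).

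The interferon genes of COPD 5 were the pattern weighed here: its list median, relative to the control mean, was 3.93, against 0.02 to 0.47 in the other COPD libraries and -0.42 to 0.39 in controls. A library from a control rat is argued against by its neutrophil list median of 4.85, since controls lay between -0.13 and 0.11. A larger mitochondrial share is argued against by its share of 36.6%, within the 33.7% to 65.0% of the other COPD libraries. Such a share would lower and not raise the FPKM of other genes, so it was no likely cause from the start. No biological explanation was tested, and a response of that rat, an infection included, may remain open beside handling of the sample.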

How the results depend on the processing

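Of 5608 values for 188 gene results under the alternatives, 5563 kept direction and side of the threshold, 20 no longer passed, 21 newly passed and 4 reversed; of 1332 values for 43 list results, 1213 kept both, 110 no longer passed and 9 reversed. Chosen after seeing the data were the scaling to the FPKM sum of all genes and without mitochondrial genes, the averaging of WDD 4 and WDD 5 and the omission of COPD 1 and COPD 5. Leaving out each library in turn gave 9378 to 10190 genes for COPD against control, 7699 to 8752 for WDD against COPD and 3975 to 6075 for WDD against control, with 18 to 24, 16 to 22 and 5 to 7 lists. It gave 6822 to 7697 genes of opposite sign and a correlation of -0.84 to -0.80. A minimum log2 fold change of 1 left 5840, 3314 and 1382 genes by construction. The cause was not tested for the following. An estimated correlation left 1, 1 and 0 lists (3 at an unadjusted p under 0.05 in the last), and fry called 42, 37 and 13. Genes of opposite sign were 4777 after median-of-ratios scaling and 4095 under quantile normalisation, which also gave 5379 genes for WDD against COPD and 13 lists for WDD against control. Library weights gave 8209 genes for WDD against control, and only the 2 groups compared gave 7211. No filter gave 26 lists for WDD against COPD and 8 for WDD against control, and scaling without mitochondrial genes gave 9 for the latter. Scaling to the FPKM sum of all genes gave 7885 genes and 13 lists for WDD against control. In COPD against control, Rpl3 turned from -0.58 to 0.34 and Rpl5 from -0.51 to 0.42 after median-of-ratios scaling, and the ribosomal list median from 0.80 to -0.085 under quantile normalisation. Cyp1b1 in WDD against COPD, 0.46 and not called, was -0.074 after median-of-ratios scaling and -0.16 under quantile normalisation. It was called at 0.59 without COPD 2, without COPD 3 and after scaling to the FPKM sum of all genes (adjusted p = 0.0375, 0.0348 and 0.0301, limma), and was 0.30 and not called without COPD 1 or COPD 5. In fry, which tests the genes of a list and not their place among others, the direction was opposite to that of camera in COPD against control for NRF2 oxidative stress response (relative median 0.90), MAPK and AP-1 genes (0.34), inflammasome (0.54), cell cycle (0.59) and hypoxia (0.83), and in WDD against COPD for NRF2 oxidative stress response (-0.51), cell cycle (-0.57) and hypoxia (-0.85). Averaging WDD 4 and WDD 5 gave 9721, 7880 and 4107 genes, leaving out COPD 1 and COPD 5 gave 9998, 8174 and 6925, and the replicate block 9747, 8181 and 4637. Without COPD 5, the lists of MAPK and AP-1 genes, matrix metalloproteinases and hypoxia no longer passed in COPD against control (adjusted p = 0.05, 0.0558 and 0.0525, camera), nor did MAPK and AP-1 genes without control 5 (0.0519), where their relative median of 0.34 was 0.18, against 0.53 without control 1 and 0.40 without COPD 5. Omitting COPD 5 also moved the apoptosis and hypoxia list medians from 0.80 to 0.53 and from 0.83 to 0.51 in COPD against control and the hypoxia median from -0.85 to -0.54 in WDD against COPD. The cell cycle list, at an adjusted p of 0.0499, no longer passed in 9 of the omissions of a library (0.0512 to 0.106). Under all 29 settings run in camera with the preset correlation, 9 of 21, 11 of 17 and 4 of 5 lists were called. Limits set by read depth were not analysed here.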

Other observations

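Protease inhibitors and antioxidant enzymes, whose balance with proteases and oxidants is studied in this disease, split by gene. Of 13 protease inhibitor genes, 5 rose and 7 fell in COPD against control lungs, the same adjusted over the list alone, and the list did not pass (adjusted p = 0.0648, camera). Serpinb1a, an inhibitor of neutrophil elastase, stood at 49.3 ± 3.82, 1420 ± 553 and 56.9 ± 5.92 FPKM in control, COPD and WDD lungs (mean ± SD, n = 5), log2 fold changes of 4.71 ± 0.24 (± SE) and then -4.51 ± 0.24. Timp1 rose by 3.29 ± 0.34 in COPD lungs, whereas Timp2 fell by 2.79 ± 0.21. In WDD against COPD lungs 8 of the 13 rose and 5 fell, also adjusted over the list alone (adjusted p = 0.168, camera), with Serpina1, an elastase inhibitor, higher by 2.75 ± 0.32. Of 13 antioxidant enzyme genes, 3 rose and 7 fell in COPD lungs, also adjusted over the list alone, against 8 and 3 after median-of-ratios scaling (adjusted p = 0.0760, camera). The mitochondrial Sod2 rose by 3.39 ± 0.28 and Prdx5 by 2.42 ± 0.22, whereas Prdx6 fell by 2.10 ± 0.19 and Gpx3 by 1.86 ± 0.26.

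Most measured genes of antigen presentation, alveolar type 2 cells and the circadian clock fell in COPD lungs and rose in WDD against COPD lungs, though none of these lists passed camera. Most genes outside these lists moved likewise: of all 13172 tested, 8749 were lower in COPD lungs and 7526 higher in WDD against COPD lungs. Of 12 MHC class II genes, 10 fell and then 9 rose (adjusted p = 0.254 and 0.0657), with Cd74, the invariant chain, at 1686 ± 185, 479 ± 181 and 1745 ± 139 FPKM in control, COPD and WDD lungs. Of 14 alveolar type 2 genes, 11 fell and 1 rose, and then 10 rose (adjusted p = 0.194 and 0.168). Sftpb, a surfactant protein, stood at 3600 ± 547, 712 ± 205 and 2388 ± 252 FPKM. Of 17 clock genes, 14 fell and 1 rose, and then 14 rose and 1 fell (adjusted p = 0.0803 and 0.132), with Per3 at 36.3 ± 2.32, 3.61 ± 1.92 and 20.8 ± 6.01 FPKM. Adjusted over the list alone, these counts differed for 1 type 2 gene, lower in WDD than in COPD lungs. After median-of-ratios scaling 7 MHC class II, 8 type 2 and 11 clock genes fell and 1, 3 and 2 rose in COPD lungs, and in WDD against COPD lungs 7, 9 and 9 rose and 0, 3 and 2 fell. Of 7 genes answering to the aryl hydrocarbon receptor, a sensor of smoke constituents, 5 fell and then 3 rose, also adjusted over the list alone (adjusted p = 0.946 and 0.991, camera). After median-of-ratios scaling 3 fell and 2 rose, and then 2 rose and 2 fell. Cyp1a1 changed by -2.42 ± 0.38 and 2.51 ± 0.38, Aldh3a1 by -1.56 ± 0.33 and 1.66 ± 0.33, and Nqo1 by -0.95 ± 0.15 in COPD lungs. In COPD lungs Aldh3a1 was at -0.54 and not called under quantile normalisation (adjusted p = 0.161, limma), and Nqo1 at -0.05 and not called after median-of-ratios scaling (adjusted p = 0.801, limma). The genes AABR07015057.1 and AABR07015081.2, chosen after their values were seen, stood at 4.74 ± 2.41 and 5.80 ± 2.24 FPKM in control, 306 ± 107 and 277 ± 71.3 FPKM in COPD and 330 ± 99.8 and 282 ± 40.5 FPKM in WDD lungs.

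Of the tests that follow, those on the mitochondrial share and on library scaling, and the simulated splits, were chosen after the results were seen. Most genes were lower in COPD than in control lungs, with a median log2 fold change of -0.81. Mitochondrial transcripts taking a larger share are argued against as the whole cause. The other genes would then share a common shift that scaling to their own FPKM sum removes. The median after that scaling was -0.65, against -0.81 on the deposited values. With mitochondrial genes in the sum it was -1.27, where the sum itself was larger in COPD than in control lungs (mean 753900 against 509400). Loss of long transcripts through lower RNA integrity may contribute, since long housekeeping transcripts differed from short ones by -2.15 between COPD and control lungs. WDD lungs had -1.67 with a median of -0.23 for all genes, so the measure and that median were not proportional. Cell makeup of the exposed lung stays open and was not tested.

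Fold changes of WDD against COPD were opposite to those of COPD against control. With the shared COPD libraries split between the comparisons, the correlation was -0.585 or lower on the deposited values. Simulated unchanged groups, split likewise, had a mean of -0.0491 but reached -0.677, so this correlation by itself does not decide. With all COPD libraries in both comparisons, the covariance was -0.691, against a lowest simulated value of -0.0864. Its median was -0.645 with the COPD libraries split. These covariances argue against the shared libraries as the whole cause, though the simulations gave the groups equal spread. After median-of-ratios scaling the correlation with the COPD libraries split was -0.614 or lower, beyond the lowest simulated value of -0.499 (mean -0.00172). That argues against the shared libraries as the whole cause after this scaling, though the simulations gave the groups equal spread. Library scaling moved the count of such genes from 7373 to 4777 after median-of-ratios scaling. Independent lists of the same sizes would share 845 and 1003 genes in these directions, but both comparisons behind the 4777 use the COPD libraries. With the COPD libraries split, 2915 to 3792 genes remained after that scaling, 1.93 to 2.90 times as many as independent lists would share. These counts argue against library scaling as the whole cause. A difference in RNA integrity between the groups may contribute and stays open, since the long-minus-short measure differed by 0.48 between WDD and COPD lungs, and an effect of the decoction is open beside it.

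Groups were also redrawn, with 100 splits of the libraries per result, the real one included. For genes called, only the real split, 1 of 100, reached 9833 in COPD against control (highest other 4713), 8399 in WDD against COPD (highest other 1280) and 4915 in WDD against control (highest other 1889). The same held for the 7373 genes of opposite sign, reached by 1 of 100 (highest other 643). A share of 1 of 100 is the smallest that these draws can give. Redrawn groups also mix the real ones, so the real difference adds to their spread and lowers their gene counts. How often unchanged groups would give such counts is therefore not measured here. For the lists, 13 splits gave at least the 21 of COPD against control (highest other 23), 31 the 17 of WDD against COPD (highest other 26) and 94 the 5 of WDD against control (highest other 20). With 5 libraries per group, no redrawn split mixes the real groups evenly, so each keeps part of their difference and can call lists through it. These draws therefore neither exclude nor measure chance for the number of lists, and they do not test any single list. The same limit holds for the correlation of -0.826, which 14 splits reached (lowest other -0.92), so chance is not excluded there either.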
